A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

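RNA was transcribed with T7 RNA polymerase from a synthetic pool, reverse-transcribed with TGIRT-III and ligated to an adaptor at the cDNA, per the labels' protocols. STAR and SAMtools are named in the submitters' processing notes, without versions or roles. The genome build and annotation are not given in the sources used here. The deposited data are 1 table for the whole series, with 1 row per position of each pool RNA, giving the RNA's name, its reference base, 3 coverage columns and 3 columns named as mutation rates.

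The authors deposited the reference base of each position as a letter, and this column and the RNA names were the only columns used. The 6 value columns were not used because their names give a replicate number without a condition, and each number is shared by 1 denatured, 1 untreated and 1 DMS-treated refolded library. No condition was inferred from the values. The columns named as mutation rates hold whole numbers, so they look like counts of mutated reads. As a result none of the 9 planned results on mutation rates, DMS-reactive positions, leader reactivity, gene lists by reactivity and reactivity against predicted pairing was computed, and the depth per library is not given. The table stops within an RNA after 1048575 positions, so the pool is held only in part, and nearly all wild-type leaders present belong to Watson-strand genes.

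The rows of each RNA were joined in file order to give its sequence. The leader was defined as the bases after the GGG at the 5′ end and before the lower-case ATG of a wild-type RNA. In upstream AUG variants the start codon was taken as the lower-case agt at the length that the name gives or 1 nt before it. For 1 of 1334 variants no single such codon was found, and it was left out. The number in the name equalled the leader length in 219 of 219 wild-type leaders of Crick-strand genes and was 1 nt longer than the leader in 4090 of 4093 of Watson-strand genes with a number above 0, so leader lengths were measured on the sequences. Gene symbols came from the RefSeq gene table of assembly R64, matched by locus tag (2702 of 2779 genes), and none of its coordinates was used.

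Each complete RNA, in capitals and with U for T, was folded with ViennaRNA 2.7.2 at 30 °C, the temperature at which the RNA was incubated per the labels. The minimum free energy structure and the base pair probabilities were kept, and the unpaired probability of a base was taken as 1 minus the sum of its pair probabilities. These are predictions without reactivity data, salt or protein. Leader features were length, A, U and GC content, a run of at least 6 U, a run of at least 8 A, the number of lower-case agt codons in the leader, which stand for upstream AUGs, A at the third base before the start codon, and the mean unpaired probability of the leader and of a window of 10 nt on each side of the start codon. Leaders under 10 nt were left out, and several leaders of 1 gene were averaged.

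The 8 gene lists were fixed before the data were examined: ribosomal proteins, glycolysis, initiation factors, elongation factors, chaperones, oxidative phosphorylation, cap-independent activity in invasive growth, and regulation by upstream reading frames or structure. The 6 lists with at least 5 genes present were compared with all other genes, for each of 10 features, by a two-sided permutation test of the mean with 100000 draws, adjusted by Benjamini-Hochberg over the 60 tests. Enumerating all lists of 7 genes was not feasible. Paired differences within genes were tested by flipping signs at random 100000 times. On simulated data made from the leader values of 2273 genes, lists of 7 genes shifted by 1 SD were called in 62.5% of 40 simulations at an unadjusted p below 0.05 and lists of 70 genes in 100%, and unshifted lists in 2.5% and 7.5%. The sign-flip test called 6.67% of 60 unshifted and 100% of 60 sets of 200 simulated genes shifted by 0.3 SD.

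The rule for named genes fixed before the data were examined needs a reactivity test and could not be applied. A new rule, written after the file was read and before any folding, named the 10 highest and 10 lowest genes by unpaired probability of the longest leader of at least 30 nt, among genes with a symbol, and the highest and lowest member of each list. An upstream AUG shared by leaders of different length was read in the longest; this was set after a first result, with a smaller difference in A, had been seen with a shorter one, and the shortest leader is kept as an alternative. The other comparisons of sequences and predicted structures were also chosen after the file was read. Their alternatives were the longest leader per gene, each leader on its own, leaders of at least 20 nt, upstream AUGs restored before folding, folding at 37 °C, Watson-strand or Crick-strand genes alone, 1 upstream AUG per gene, a window of 5 nt and stem-loops before the start codon alone. The last 10 nt before the start codon were at first compared with 2 other windows; all 7 others were compared after those results were seen, and the adjustment covers the 7. Genes are not replicates of an experiment. SDs describe the spread between genes, and p-values refer to genes rather than to repeated experiments. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.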

Results

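The series describes DMS probing of RNA structure in a synthetic pool of Saccharomyces cerevisiae 5′ leaders. Dimethyl sulphate (DMS) methylates unpaired A and C, and the modified bases are read as mutations after reverse transcription. By the labels there were 9 libraries in 3 groups of 3 replicates: RNA denatured at 95 °C for 2 min and treated with DMS, RNA refolded and incubated at 30 °C for 2 min with DMS, and RNA refolded in the same way without DMS. The design implies a comparison of refolded with untreated RNA and of refolded with denatured RNA. Neither comparison was made. The deposited table has 6 columns of values, 3 named as coverage and 3 named as mutation rates, whose names carry a replicate number and no condition, and each number belongs to 3 of the 9 samples. These columns were not used, so no depth, reactivity or replicate error is given, and every value below describes the sequences of the pool or a structure predicted from them. DMS reactivity was not analysed here.

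The table held 5762 pool RNAs of 2779 genes, and 2702 of these genes matched a locus tag of the RefSeq gene table. Each complete RNA began with GGG, carried a 159-nt insert and ended with a constant stretch of 20 nt. The table stopped after 1048575 positions, which left the last RNA cut off after 73 nt. The RNAs were of 3 kinds. Wild-type leaders made up 4384 RNAs of 2371 genes, leaders that kept an upstream AUG made up 1334 RNAs of 761 genes, and RNAs with an inserted stem-loop numbered 44, of 12 genes. Of the wild-type leaders, 4165 (95.0%) belonged to genes named on the Watson strand and 219 to genes named on the Crick strand, so the values for wild-type leaders describe mostly Watson-strand genes. Over the 4383 complete wild-type RNAs the leader, from the nucleotide after GGG to the start codon, had a median length of 41 nt with quartiles of 23 and 65 nt and a maximum of 122 nt. More than 1 leader was present for 1347 of 2370 genes. No RNA of GCN4, the transcription factor of amino acid starvation, of PAB1, which encodes the poly(A)-binding protein, or of TIF4631, which encodes eIF4G1, was among the RNAs analysed. The file gives no genomic coordinates or genome build, so positions are counted from the start codon.

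Wild-type leaders carried no upstream AUG, and each variant carried a single one. No complete insert held an ATG in capitals, and each of the 4384 wild-type RNAs held exactly 1 ATG in lower case, at the start codon. Other ATGs were written as agt in lower case. Such a codon lay in 515 of 4383 wild-type leaders (11.7%), from 355 of 2370 genes. The 1334 upstream AUG variants each held exactly 1 ATG, in the leader. In all of them, the last number of the name equalled the count of lower-case codons before that ATG. For the 515 parents whose wild-type leader was present, the number of variants equalled the number of agt codons in all 515. Apart from the upstream codon and the start codon, 642 variants compared with their wild-type RNA differed from it no further than 12 nt from the insert's end. Of these, 622 differed only within the last 11 nt.

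Upstream AUGs had U at the third base before the codon most often, whereas start codons of the same genes had A there most often. A purine, most often A, at this position is the known context of efficient start codons in yeast. Among 799 distinct upstream AUGs with 3 or more leader bases before them, U was found at 365 (45.7%, 95% Wilson interval 42.3 to 49.1) and A at 185 (23.2%, 20.4 to 26.2). At the start codons of the 632 genes concerned, A was found at 328 (51.9%, 48.0 to 55.8), G at 147 (23.3%, 20.1 to 26.7) and U at 90 (14.2%, 11.7 to 17.2). Averaged per gene, the share of A was 30.5 percentage points lower at upstream AUGs (SE 2.45, n = 632 genes; two-sided sign-flip permutation test, p = 1e-05, the smallest that 100000 draws can give). Over all 2346 genes whose longest wild-type leader reached this position, 61.3% had A there, against 42.5% at the base before it and 41.8% at the base after it. The intervals treat sites as independent.

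**Figure D1:**
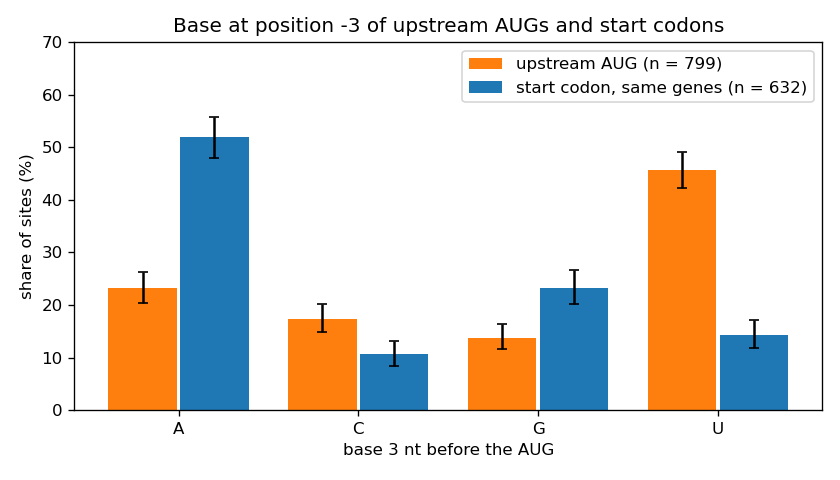
Share of sites (%) with each base 3 nt before the AUG, for 799 distinct upstream AUGs (orange) and the 632 start codons of the same genes (blue), with 95% Wilson intervals as error bars. U leads at upstream AUGs with 45.7%, and A leads at start codons with 51.9%.

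Upstream AUGs lay in the reading frame of the start codon less often than in either other frame. Of 964 distinct upstream AUGs in 760 genes, 229 were in frame (23.8%; exact two-sided binomial test against equal frames, p = 9.28e-11). The other frames held 371 and 364. Equal frames are not a neutral expectation if start codons were assigned as the first AUG of a reading frame. How they were assigned was not examined. The distance to the start codon had a median of 42 nt and ran from 3 to 122 nt. A stop codon in the frame of the upstream AUG came before the start codon for 193 of the 229 in-frame upstream AUGs (84.3%), against 380 of the 735 in the other frames. The predicted unpaired probability in a window of 10 nt on each side of the codon was 0.442 ± 0.115 at upstream AUGs and 0.448 ± 0.119 at the start codons of the same RNAs, which these variants carry as AGU (mean and SD over 518 genes). The mean difference was not told apart from 0 (−0.00624, SE 0.00665, sign-flip permutation test, p = 0.348). Its direction turned with a window of 5 nt, over the 593 genes that window allows (0.0132, sign-flip permutation test, p = 0.125). It also turned over the sites of the wider window (0.0154, 518 genes, sign-flip permutation test, p = 0.0898).

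Leaders of ribosomal protein genes were short and rich in A, and held fewer of the AGU codons that stand in the pool for upstream AUGs than other leaders. Complete wild-type RNAs were present for 79 of the 132 listed genes, which encode the proteins of both ribosomal subunits. Their mean leader length was 27.2 ± 10.6 nt against 49.0 ± 25.3 nt for all other genes (SD, n = 79 and 2194). The A content was 51.2% ± 10.4 against 38.9% ± 9.99, the U content 17.9% ± 11 against 25.2% ± 9.06 and the GC content 30.9% ± 8.22 against 35.8% ± 8.16. Such a codon was present in the leaders of 1 of the 79 genes, against 354 of the 2194 others (16.1%; mean per leader 0.0127 against 0.158), and A stood 3 nt before the start codon in 67 of 79 (84.8%, against 60.8% of the others). The predicted unpaired probability averaged over the leader was 0.555 ± 0.136 against 0.489 ± 0.110, with 53 of 79 genes above the median of all genes. RPL22A had the highest value of the list, 0.889 for a 20-nt leader with 65% A, and RPS18A the lowest, 0.285 for a 20-nt leader with 50% A. Around the start codon the value was 0.517 ± 0.104 against 0.473 ± 0.112. These differences passed a two-sided permutation test with 100000 draws and Benjamini-Hochberg adjustment over 60 pairs of list and feature (adjusted p = 0.00012 for length, A, U, GC and leader pairing, 0.0002 for A before the start codon, 0.00562 for pairing around it and 0.0212 for the AGU codons). After a linear regression on A content, U content and length the difference in leader pairing no longer passed (−0.00185, SE 0.0137; permutation test, adjusted p = 0.867). The difference in pairing around the start codon was not put through this regression. Runs of at least 6 U (2 of 79 genes) and of at least 8 A (0 of 79) did not differ by this test. Many of these genes are duplicated pairs, and the test treats them as independent. The count of AGU codons was not adjusted for leader length, and a shorter leader has room for fewer.

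The listed glycolytic and chaperone genes that were present also had A-rich leaders, predicted to be more open than those of other genes. The 7 glycolytic genes present as wild-type leaders were HXK2, GLK1, TDH1, PGK1, ENO1, ENO2 and CDC19, of 18 listed. Their A content was 50.8% ± 6.01 against 39.3% ± 10.2 (SD, n = 7 and 2266; permutation test, adjusted p = 0.0188) and their GC content 27.0% ± 7.15 against 35.7% ± 8.21 (permutation test, adjusted p = 0.0262). The predicted unpaired probability was 0.632 ± 0.102 over the leader, against 0.491 ± 0.111 (permutation test, adjusted p = 0.00827), and 0.608 ± 0.0766 around the start codon, against 0.474 ± 0.112 (permutation test, adjusted p = 0.00972). ENO1, an enolase gene, had the highest leader value of 0.758, and PGK1, the phosphoglycerate kinase gene, the lowest of 0.456. The 6 chaperone genes with a leader of at least 10 nt were HSP104, HSP26, HSP12, HSC82, SSA1 and HSP42, of 17 listed. They had 54.6% ± 7.98 A (n = 6; permutation test, adjusted p = 0.0024), 25.9% ± 7.34 GC (permutation test, adjusted p = 0.0212) and an unpaired probability of 0.618 ± 0.0965 (permutation test, adjusted p = 0.0262). HSP12, a small membrane-associated stress protein gene, had the highest value of 0.791, and HSC82, which encodes a constitutive Hsp90, the lowest of 0.502. All 6 lay above the median of all genes, as did 6 of the 7 glycolytic genes. Chaperone genes off the list, such as CCT4, a chaperonin subunit gene with 0.266, were counted among the other genes. The result therefore holds for the listed genes and not for chaperones as a class. With Watson-strand genes alone the GC difference of the chaperones no longer passed (permutation test, adjusted p = 0.0790, 5 genes). Around the start codon the chaperones had 0.586 ± 0.0985 against 0.474 ± 0.112, which did not pass (permutation test, adjusted p = 0.0571). After the regression on A content, U content and length the differences in leader pairing no longer passed for glycolytic genes (0.0780, SE 0.0360; permutation test, adjusted p = 0.0968) or chaperone genes (0.0395, SE 0.0312; permutation test, adjusted p = 0.451). The differences around the start codon were not adjusted in this way.

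No feature passed for the translation factors or for oxidative phosphorylation. All 7 elongation factor genes listed were present, and all had A 3 nt before the start codon, as did all 7 glycolytic genes. Neither share passed after adjustment (permutation test, p = 0.0482 and adjusted p = 0.161 for each). Among elongation factors the predicted unpaired probability ran from 0.355 in YEF3, the elongation factor 3 gene, to 0.733 in HYP2, the eIF5A gene. Among 7 of 21 initiation factor genes it ran from 0.392 in DED1, which encodes a DEAD-box helicase, to 0.609 in SUI3, which encodes eIF2β. Among 7 of 23 oxidative phosphorylation genes it ran from 0.419 in ATP3, a subunit of the ATP synthase, to 0.832 in CYC1, the cytochrome c gene. The 2 genes of the list regulated by upstream reading frames or structure with wild-type leaders present had values of 0.610 (HAC1) and 0.625 (CPA1), too few for a test. These leaders held no AGU codon in place of an upstream AUG. The values therefore describe no leader with an upstream AUG. None of the 12 listed genes with reported cap-independent activity in invasive growth was among the complete wild-type RNAs.

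**Figure D2:**
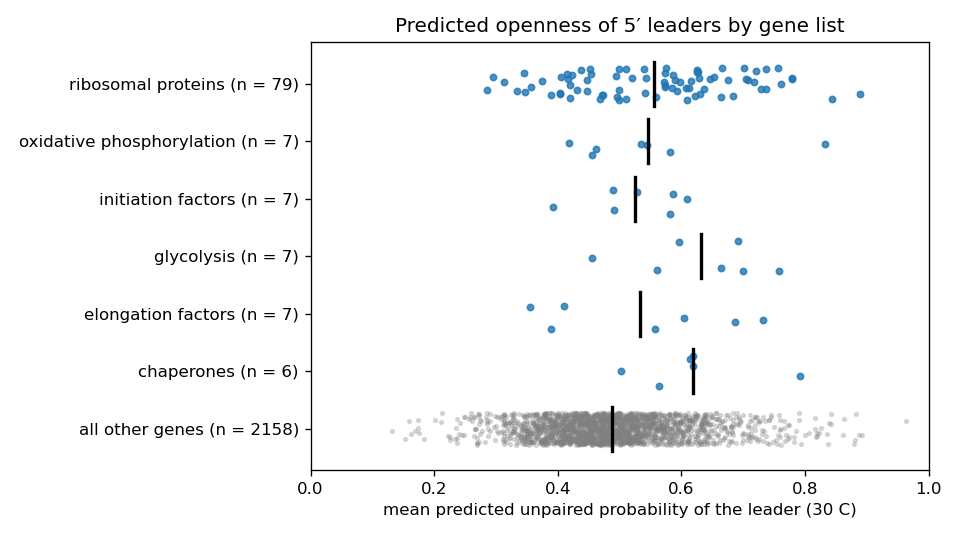
Predicted unpaired probability at 30 °C averaged over each gene's leaders (x axis, from 0 to 1), with 1 point per gene, vertical jitter for display and black bars at the means. The means are 0.632 for glycolysis, 0.618 for chaperones and 0.555 for ribosomal proteins, against 0.488 for the 2158 genes on no list.

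Across 1623 named genes with a leader of at least 30 nt, the predicted unpaired probability of the longest leader was 0.488 ± 0.0985 (SD). The highest values were found in YAT2 (0.895), a carnitine acetyltransferase gene, and CAR1 (0.882), the arginase gene. DSF1 (0.837), CYC1 (0.832), ALD6 (0.822), which encodes an aldehyde dehydrogenase, MCO14 (0.817), MIX17 (0.812), MFA2 (0.799), an a-factor gene, EGT2 (0.790) and NNF1 (0.787) followed. A made up 51.1% or more of 9 of these 10 leaders, the exception being MFA2 with 37.2%. The lowest values were found in GAA1 (0.159), a GPI transamidase gene, and SFT2 (0.223). ATG5 (0.248), an autophagy gene whose leader held 4 AGU codons in place of upstream AUGs, ATG29 (0.257), LEA1 (0.264), CCT4 (0.266), a chaperonin subunit gene, LHP1 (0.266), MCM5 (0.274), RPT5 (0.275), which encodes a proteasomal ATPase, and TAG1 (0.277) followed.

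Predicted pairing in the 10 nt before the start codon was lower than more than 30 nt upstream or in the coding part, and close to that of the windows between. Over 929 genes with a leader of at least 60 nt, the unpaired probability was 0.506 ± 0.190 (SD) in the 10 nt before the start codon, 0.499 ± 0.205 from 20 to 11 nt before it and 0.495 ± 0.197 from 30 to 21 nt before it. It was 0.474 ± 0.194 from 40 to 31 nt before the start codon and 0.437 ± 0.174 in the first 10 nt after it. The last 10 nt did not differ by the test from the nearest windows upstream (differences 0.00662, SE 0.00852, and 0.0107, SE 0.00885; sign-flip permutation test, adjusted p = 0.438 and 0.264 over 7 windows). They exceeded the window from 40 to 31 nt by 0.0322 (SE 0.0087, higher in 488 of 929 genes; sign-flip permutation test, adjusted p = 0.000364). They exceeded the first 10 nt after the start codon by 0.0689 (SE 0.00846, higher in 563 genes; sign-flip permutation test, adjusted p = 1.75e-05). Base composition varied along these positions, with A in 61.3% of 2346 genes 3 nt before the start codon. The windows were not adjusted for composition, so position and composition cannot be told apart here.

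**Figure D3:**
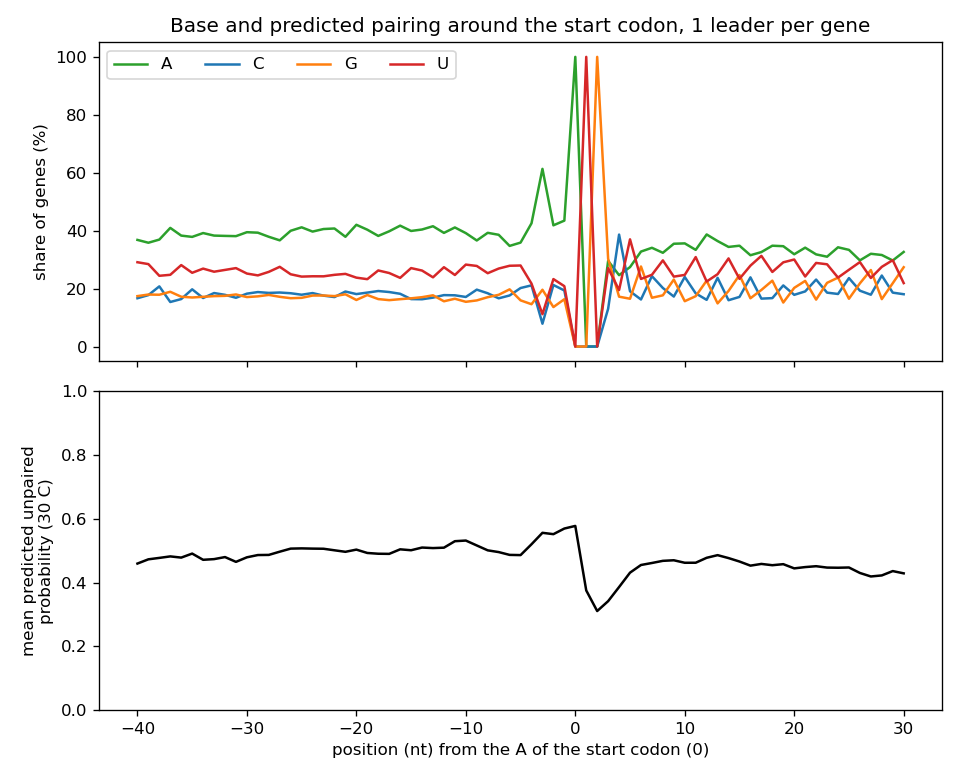
Share of genes (%) with each base (upper panel) and mean predicted unpaired probability at 30 °C (lower panel) by position in nt from the A of the start codon, from the longest leader of each gene with upstream codons restored for the bases. A peaks 3 nt before the start codon at 61.3%, and the unpaired probability is 0.578 at the A of the start codon and 0.311 at its G.

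The stem-loop set carried 6 hairpins, placed before the start codon in 30 RNAs and after it in 14, each with AUCUU at its centre. In the DNA letters of the file they were CCAACATCTTGTTGG (SL5), CGCACATCTTGTGCG (SL7), CGAAGAACTATCTTAGTTCTTCG (SL11), CCAGAATACATCTTGTATTCTGG (SL12), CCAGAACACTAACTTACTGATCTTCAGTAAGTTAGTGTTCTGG (SL31) and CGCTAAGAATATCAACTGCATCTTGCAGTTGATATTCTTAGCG (SL31s). Their predicted folding energies at 37 °C were −4.7, −6.3, −10.8, −11.6, −31 and −30.4 kcal/mol in this order. In 38 of 44 RNAs the hairpin began at a distance from the insert's start equal to 3 times the last number of the name, and in the 6 exceptions it lay after the start codon. Of the 14 RNAs with the hairpin after the start codon, 5 came from VPS21 and 4 from PHA2, whose wild-type parents were not analysed here, and 5 had a parent. The predicted minimum energy structure of the whole RNA at 30 °C held the hairpin exactly as it folds alone in 31 of 44 RNAs. By kind, it was so held in 3 of 8 RNAs for SL5 and in 5 of 7 each for SL7, SL11 and SL12. For SL31s it was 7 of 9 and for SL31 6 of 6. In the 3 SL5 RNAs that held it, the hairpin lay after the start codon. All 31 RNAs whose wild-type parent was present were predicted to be more stable than it. An added stem makes such a gain likely beforehand. The insert stays at 159 nt, so the hairpin takes the place of coding sequence, and the change reflects both. RNAs of 1 parent share its energy and are not independent. Neither SL5 RNA with a parent held the hairpin as it folds alone, so the SL5 change is not that of the intact hairpin. The mean change was −5.92 kcal/mol for SL5 (SD 0.827, 2 RNAs of 2 parents), −6.73 for SL7 (SD 3.04, 5 RNAs of 3 parents), −5.31 for SL11 (SD 3.68, 7 RNAs of 5 parents), −5.12 for SL12 (SD 4.13, 7 RNAs of 4 parents), −17.7 for SL31 (SD 2.96, 2 RNAs of 1 parent) and −22.5 for SL31s (SD 2.96, 8 RNAs of 5 parents). With the hairpin before the start codon alone it was −8.55 for SL7 (SD 2.02, 3 RNAs), −5.56 for SL11 (SD 3.97, 6 RNAs) and −22.1 for SL31s (SD 3.18, 6 RNAs), and no hairpin of the remaining kinds with a parent lay after the start codon.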

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

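All alternatives reported here were chosen after seeing the data. Of the comparisons of DMS reactivity set out before the data were examined, 9 results and 51 other settings were not run. No paired analysis was possible because no value column could be matched to a sample. Each of 15 called differences in leader features, of 60 tested, was recomputed under the settings that apply to its feature. Some settings left the listed genes unchanged and altered only the other genes. All 7 glycolytic genes were Watson-strand genes, and no glycolytic or chaperone leader counted held an AGU codon to restore. In 69 of 70 recomputations direction and call were kept, the exception being the GC content of chaperone leaders with Watson-strand genes alone (−8.71 percentage points, permutation test adjusted p = 0.0790, 5 genes instead of 6). The number of called differences ran from 14 to 18. The most came with each leader counted on its own, where leaders of 1 gene enter as if independent. The lower share of A before upstream AUGs (−30.9 to −29.0 percentage points, the last with shared sites read in the shortest leader, 588 genes) and the low in-frame share (22.4 to 25.5%) kept their calls, also with 1 upstream AUG per gene and on either strand alone. The difference in predicted pairing between upstream AUGs and start codons was not called under any setting and turned sign with a window of 5 nt (0.0132, 593 genes instead of 518), also over the sites of the wider window (0.0154, 518 genes), so the added genes did not bring the turn. Folding at 37 °C left all 31 stem-loop RNAs more stable than their parents, and every mean change became smaller, to −5 kcal/mol for SL5, −5.38 for SL7, −4.77 for SL11, −4.8 for SL12, −15.8 for SL31 and −20.4 for SL31s; for SL5 alone, with 2 RNAs, the move exceeded the SD at 30 °C. Leaving out hairpins after the start codon moved the SL7, SL11 and SL31s means by less than their SDs. No depth limit can be given because coverage was not used.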

Other observations

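The test of in-frame upstream AUGs with and without a stop was chosen after the counts of closed sites were seen, the percentile of stem-loop parents was chosen after their values were seen, the limit on the share of closed in-frame sites was given up after its value was seen, and the regression was set up after the list differences were seen. The limit that decides the regression was narrowed after its values were seen; under the first limit, a difference that no longer passes the test, the glycolytic and chaperone lists would also have counted as accounted for. Tests of 2 further patterns, on leader names and hairpin names, were dropped after their values were seen, and those values follow as plain values.

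The 10 wild-type parents of the stem-loop set that were present lay high among the leaders ranked by predicted unpaired probability, with a median percentile of 96.5 and a lowest of 72.8. CYC1 (99.8), ALD6 (99.8) and MFA2 (99.6), which encode cytochrome c, an aldehyde dehydrogenase and a-factor, stood highest, and RDS3 stood lowest. The size of the predicted folding energy of each hairpin alone at 37 °C, minus the number after SL in its name, ran from −0.7 to 0 kcal/mol. Leader names of Watson-strand genes gave a length 1 nt above the sequence in 4090 of 4093 wild-type RNAs with a number above 0, and names of Crick-strand genes in 0 of 219.

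U was frequent and A rare 3 nt before upstream AUGs. Base composition of the leaders was tested on the 5 other orders of A, U and G in the same leaders. U stood 3 nt before these triplets in 27.3 to 30.0% of sites, and before AUG in 45.7%, which is 15.7 percentage points above the highest of them. A stood before AUG in 23.2% and before the others in 33.5 to 37.5%. Composition alone is therefore argued against. A candidate explanation that stays open is selection against upstream AUGs in a favourable context, and another is how the pool's leaders were chosen; neither was tested.

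Upstream AUGs were rarer in frame than in the other frames. A stop came before the start codon for 84.3% of in-frame sites (95% Wilson interval 79.0 to 88.4), and 36 in-frame sites without one remained, so these were not absent. This share was under the limit of 90% set beforehand, but that limit was wrong, since a strong depletion and none both fall under it. By this share alone, extension of the protein and other reasons for the deficit cannot be told apart. Splitting the sites showed where the deficit lay: 193 in-frame sites were closed by a stop (exact Poisson interval 167 to 222), against a mean of 190 in the other frames, while 36 were open, against a mean of 177.5. The deficit thus lay in open in-frame sites, the ones that would extend the reading frame, and was not seen in closed ones. No reason for it was tested. If a start codon is defined as the first AUG of its reading frame, open in-frame upstream AUGs are left out by that definition. How the start codons were assigned was not examined, so the deficit cannot be told apart from a result of such a definition.

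The more open predicted leaders of 3 gene lists were set against base composition and length by linear regression on A content, U content and length over 2273 genes, which took up 27.2% of the variance. For ribosomal proteins the difference of 0.0659 fell to −0.00185 (SE 0.0137, above 0 in 40 of 79 genes; permutation test, adjusted p = 0.867), so composition and length are a sufficient candidate explanation. For glycolysis 0.0780 of 0.141 was left (SE 0.0360, above 0 in 6 of 7 genes; permutation test, p = 0.0323, adjusted p = 0.0968) and for chaperones 0.0395 of 0.127 (SE 0.0312, 5 of 6 genes; permutation test, adjusted p = 0.451). For these 2 lists a part beyond composition and none cannot be told apart with 7 and 6 genes.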
